A study of Homo sapiens with 3 samples.

How the data were processed

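The series holds RNA sequencing of LNCaP-abl cells 72 h after transfection by lipid reagent with a pool of siRNAs against E2F1 (1 library) or with control siRNA (2 libraries). Groups and the control numbers 0 and 1 were taken from the sample titles. Libraries were made with a TruSeq RNA v2 kit, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.4, Cufflinks 2.0.2 and the genome build hg19, with no parameters; the annotation is not given in the sources used here.

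The deposited values are log2 FPKM, 1 per gene and library, in files with no header. The lowest value in each library equals log2 of 0.1 and is shared by 1791, 1836 and 1615 genes in control 0, control 1 and siE2F1. Whether the authors added 0.1 FPKM or set a minimum is not given in the sources used here; values just above the minimum lie apart from it, as an addition would give. FPKM was therefore computed here by raising 2 to the deposited value and subtracting 0.1, which would be 0.1 FPKM too low for each gene if a minimum had been set. The sorted deposited values of any pair of libraries differ by at most 0.0653 log2 units and their median is 1.59 in each, a pattern that quantile normalization gives, although no source states that step. Such scaling forces equal distributions, so a change shared by most genes cannot be seen, and the common-median shift tried here moved no library (shift 0). Genes at the minimum are called listed at 0. Read counts were not given: depth is unknown, no counting interval can be given, and no count model was used. Fewer than 0.2% of all listed genes had identical values above the minimum in any pair of libraries (0.199%, 0.0663% and 0.124%, within 1e-09), so the 3 libraries were treated as separate.

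Values were analysed as log2(FPKM + 1), which understates the change of low genes. Genes with a mean of at least 1 FPKM over the 3 libraries were tested in R 4.3.3 with limma 3.58.1 (empirical Bayes moderation with a mean-variance trend), siE2F1 against control, two-sided, with Benjamini-Hochberg adjustment at 0.05. The spread comes from the 2 controls alone, 1 residual degree of freedom per gene, and the single siE2F1 library is assumed to vary as the controls do. The prior degrees of freedom were 1.69 over all genes tested and 3.19 without small RNA genes. No test across genes was needed for the size rule, which counts genes at least 1 log2 unit beyond both controls.

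The tests, 25 gene lists and the rule for named genes were fixed before the data were examined. The rule names E2F1, then up to 15 genes per direction with the largest log2 fold change among those that passed on the same side of both controls. Where fewer pass, the remaining places go to the genes farthest from the nearer control, given as values. From each list it takes up to 4 called members with the largest change, or 2 where none was called; small RNA genes and genes without a symbol are left out. Some list members are not reported here by name. Lists with at least 5 measured members (22 of 25) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated. The estimated variant has 1 degree of freedom in this design, so it could hardly call any list. A list's median was also ranked among 10000 random lists of the same size matched on mean expression in 50 bins. Counts adjusted over the list alone apply Benjamini-Hochberg within the list. A further 4 lists were added after top genes had been seen and are not independent of them.

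The settings varied were a pseudocount of 0.1, no filter on mean FPKM, a mean of at least 5 FPKM, a common median, quantile normalization of log2(FPKM + 1), no mean-variance trend, each control left out, and the estimated correlation. Leaving out small RNA genes (names starting with SNOR, MIR, SCARNA or RNU, host genes kept) was added after seeing the data.

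The limma step was tested on 20 sets of simulated libraries with the means of the real genes, 100 genes changed 2-fold and 100 changed 4-fold. These changed genes were drawn only from genes other than small RNA genes with control means well above the 1 FPKM filter. Recovery of changes in low genes was therefore not tested. With gene variances drawn from the fitted prior, it called 0% of the 2-fold and 20.6% of the 4-fold changes among 14401 genes, and 89.4% and 99.4% among the 13928 genes left without small RNA genes, with 7.2% and 7.36% of calls false on average. A set with no call counted as 0% false. Among 14401 genes only 8 of the 20 sets held any call, so 7.2% understates the false share in sets with calls. With each gene's own moderated variance it called 93.6% and 99.4% among 14401 genes and 100% of both sizes among 13928, with 12.8% and 19.2% of calls false, so the nominal 5% is not held in this design. This second variance model was run first, and the other was added once its false share had been seen. Camera found a list of 50 genes shifted by -0.5 in 20 of 20 sets in each setting, and called an unchanged list in at most 1 of 20. Genes were drawn independently in these sets, so they cannot show how often camera calls an unchanged list of genes that vary together.

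For checks on transcript properties, gene names were matched to GENCODE release 29 transcripts, 15092 by symbol, 3856 by Ensembl identifier and 14 by an older symbol, with 3651 unmatched. That annotation belongs to a later genome build than hg19, so no coordinates are given. The trend of log2 fold change on transcript length, GC content and mean expression was fitted with natural splines of 4 degrees of freedom each over 12444 genes, with a bootstrap of 2000 draws for the medians left. In 3′ UTRs of at least 50 bases, 15342 sequences of 7 bases found in at least 100 genes were scored in Python 3.11.15 with numpy 2.4.6. For each, z compared log2 fold changes, limited to 1.5 log2 units after regression on UTR length, base composition, transcript length and expression, between genes with and without it. The background was 200 permutations over genes. On permuted fold changes the search recovered a planted sequence as its lowest.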

Results

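RNA sequencing was used to ask how gene expression in LNCaP-abl cells differs after the transcription factor E2F1 is silenced. LNCaP-abl is an androgen-independent derivative of the LNCaP prostate cancer line, kept here in serum stripped of steroids. E2F1 binds DNA together with a DP partner and activates genes needed for entry into S phase. RNA was taken 72 h after transfection with a pool of siRNAs against E2F1 (siE2F1) or with control siRNA. There were 2 control libraries, numbered 0 and 1 in the labels, and 1 siE2F1 library, so no siE2F1 value has a replicate. The labels do not say whether the controls came from separate cultures. P-values of single genes thus measure only the spread between these 2 libraries, which may be technical. Camera p-values at the preset correlation set a list's genes against the other genes, so their units are genes, not libraries or cultures. Each library listed 22613 genes as normalized FPKM, of which 14401 with a mean of at least 1 FPKM were tested. Read counts were not given, so the depth of each library is unknown. Leaving out small RNA genes, Pearson's r across genes was 0.994 between the controls and 0.98 and 0.979 between siE2F1 and each control; genes are not independent replicates.

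E2F1 itself fell from 10.6 FPKM ± 0.0146 (SD, n = 2) in the controls to 1.68 FPKM in the siE2F1 library. Its log2 fold change was -2.12 with a standard error of 0.0605 (limma, adjusted p = 0.0311), on the log2(FPKM + 1) scale used for every fold change here. The 5 genes that the naming rule took from those that rose are each induced by interferon. OASL, a relative of the oligoadenylate synthetases, rose 15.2-fold, from 1.27 and 1.39 FPKM in the controls to 34.5 FPKM (adjusted p = 0.0191). IFIT1, which binds foreign RNA, rose from 2.88 and 2.81 to 31.0 FPKM (8.32-fold, adjusted p = 0.0191). IFI6 rose to 92.6 FPKM (7.64-fold, adjusted p = 0.0452), RSAD2, the antiviral protein viperin, to 13.4 FPKM (6.9-fold, adjusted p = 0.0232) and IFIT2 to 21.95 FPKM (5.78-fold, adjusted p = 0.0232). ARL6IP1, a membrane protein of the endoplasmic reticulum, fell from 137.5 and 145.3 to 16.4 FPKM (8.18-fold lower, adjusted p = 0.0231). TSPAN7, a tetraspanin of the cell surface, fell from 15.6 and 14.8 to 2.36 FPKM (4.82-fold lower, adjusted p = 0.0365).

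In all, 60 genes passed limma at an adjusted p of 0.05, 45 higher and 15 lower in siE2F1, and 50 of them were small nucleolar, small nuclear or micro RNA genes. Of these 50, 36 were listed at 0 in both controls and 10 at 0 in siE2F1. Such short genes have unsteady FPKM: 216 of the 473 tested (45.7%) differed at least 2-fold between the controls, against 47 of the 13928 other genes (0.337%). The 10 other genes were the 8 named above, counting E2F1, and 2 listed by Ensembl identifier, named here after their values were seen. ENSG00000244468 (TM4SF18-AS1) was at 2.19, 1.95 and 19.1 FPKM in control 0, control 1 and siE2F1, and ENSG00000260110 at 4.07, 4.02 and 0.00158 FPKM. Without small RNA genes, a choice made after seeing the data, 1467 genes passed, 581 higher and 886 lower, with a median absolute log2 fold change of 0.59, and they included all 10. With control 0 or control 1 in the place of siE2F1, 58 and 30 genes passed over all genes tested. Without small RNA genes those counts were 0 and 2, with 118 and 142 genes at an unadjusted p under 0.05 against 4658 for siE2F1. In these comparisons the spread includes the difference between siE2F1 and the other control, so low counts are partly built in. With a pseudocount of 0.1, OASL and IFIT1 were the 2 of these 10 genes that still passed; the E2F1 call was lost there (adjusted p = 0.0601) and with no filter on mean FPKM (adjusted p = 0.159), where 0 genes passed and 4862 had an unadjusted p under 0.05. Its adjusted p ranged from 0.0106 to 0.159 over all settings.

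The remaining genes far beyond both controls did not pass over all genes tested, but each passed without small RNA genes. On the higher side, 6 belong to the interferon list: IFIT3 (log2 fold change 2.47), IFI27 (2.64), ISG15 (2.15), BST2 (1.97), OAS1 (1.81) and IFI44 (1.42). The other 4 were LOC100506963 (2.56, listed at 0.014 and 0.0159 FPKM in the controls), RARRES3 (2.46), ENO1-AS1 (2.56) and IL36G (1.32), an interleukin of the IL-1 family. Control 0 and control 1 lay far apart for ENO1-AS1 (0.0133 and 0.735 FPKM) and IFI27 (1.18 and 0.351 FPKM), so their fold changes are less certain. On the lower side were the cell division genes CDCA8 (-1.54), CDC25A (-1.50) and SKA2 (-1.48), and the signalling genes NRAS (-1.47), ADAM10 (-1.45), a membrane protease, and ID1 (-1.45), an inhibitor of basic helix-loop-helix factors. CSAG2 (-2.28), ERLEC1 (-1.93), DESI2 (-1.66), EIF4EBP2 (-1.64), a repressor of translation, TTC19 (-1.55) and PLEKHB2 (-1.50) completed them. With a pseudocount of 0.1 the log2 fold change moved by over 1.5 times for low genes, to 5.47 for LOC100506963, 4.49 for ENO1-AS1, 2.60 for IFI44 and -3.93 for CSAG2. On the main scale the adjusted p ranged from 0.0528 to 0.117 for the 10 higher and from 0.0525 to 0.0974 for the 12 lower genes. The library kit does not mark strand, so reads of antisense genes such as ENO1-AS1 and TM4SF18-AS1 cannot be told from those of their partners, and CSAG2 has near-identical copies.

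**Figure D1:**
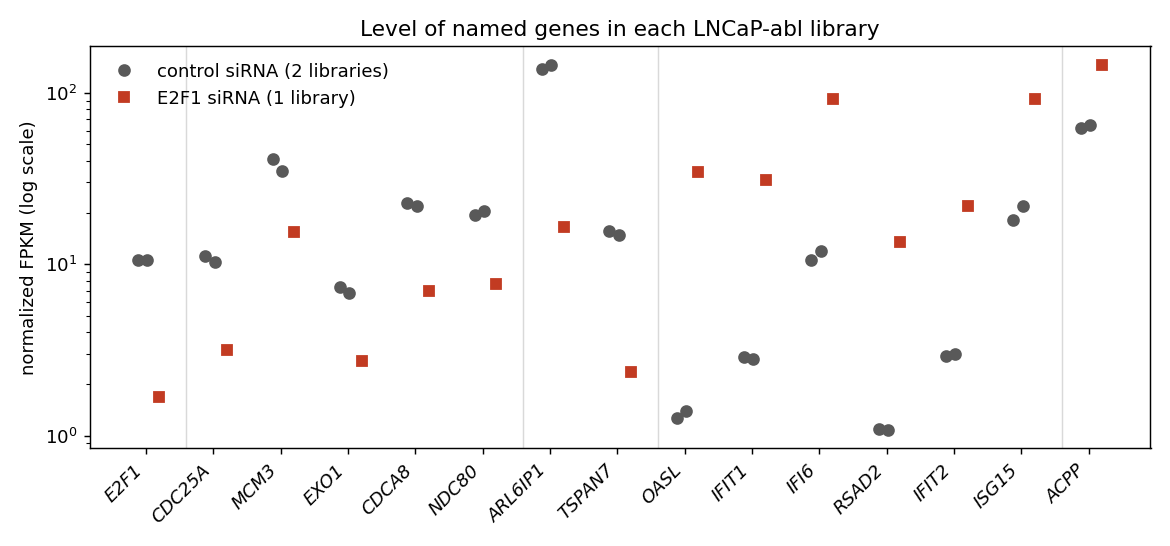
Normalized FPKM (log axis) of 15 named genes in each library, with 2 control libraries as circles and the siE2F1 library as a square. E2F1 lies at 1.68 FPKM in siE2F1 against 10.6 in each control, OASL at 34.5 against 1.27 and 1.39, and for each gene shown the gap to siE2F1 is wider than the gap between the controls.

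Genes of the cell division cycle fell together. All 68 measured members of the G2/M and mitosis list were below both controls (median log2 fold change -0.57; median difference between the controls 0.004), where chance alone puts siE2F1 lowest for 33.3% of genes and 39.7% of all genes tested were lowest there. Of the 56 members of the G1/S and DNA replication list, 53 were below both controls (median -0.55, controls -0.04), and of the 31 members of the homologous recombination and Fanconi repair list, all 31 (median -0.33, controls -0.02). Adjusted over the list alone, 62, 48 and 19 members fell and none rose, against 0 over all genes tested and 54, 41 and 11 without small RNA genes. In a camera test with a preset inter-gene correlation the adjusted p was 1.74e-24 for G2/M, 3.55e-19 for G1/S and 5.57e-11 for repair, and each median lay below those of 10000 random lists matched on expression. With an estimated correlation, which leaves 1 degree of freedom in this design, none of the 5 lists called here was kept (adjusted p = 0.723 for each). A call was nearly out of reach with 1 degree of freedom. The loss therefore cannot show whether correlation between genes removes these calls.

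The members that moved furthest on the log2(FPKM + 1) scale, which understates the change of low genes, span these steps. CDC25A, a phosphatase that activates cyclin-dependent kinases, was at 11.2 and 10.3 FPKM in the controls and 3.15 in siE2F1, and MCM3, a subunit of the replicative helicase, at 41.3, 34.8 and 15.4 FPKM. CDCA8 (borealin, of the chromosomal passenger complex) was at 22.7, 21.9 and 7.01 FPKM and NDC80, of the kinetochore, at 19.4, 20.4 and 7.65 FPKM. In the repair list EXO1, an exonuclease, was at 7.41, 6.84 and 2.74 FPKM and RAD54L, a DNA-dependent ATPase, at 10.3, 8.68 and 4.50 FPKM. The E2F family and pocket protein list, which leaves out E2F1, was also called lower (9 of 12 members below both controls, median -0.28, controls -0.05, camera adjusted p = 0.0483). Adjusted over the list alone 2 members fell, with E2F7 at -0.97 (-1.64 with a pseudocount of 0.1) and E2F5 at -0.78 the furthest, and 0 over all genes tested. This call was lost among genes of at least 5 FPKM (adjusted p = 0.311) as well as with an estimated correlation (adjusted p = 0.723).

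Interferon-response genes rose as a group. Of 33 measured members, 29 were above both controls and 2 below (median log2 fold change 0.59; median difference between the controls 0.001), where 43.7% of all genes tested were above both. Over all genes tested 5 members rose, 21 rose adjusted over the list alone and 19 without small RNA genes, and none fell. The camera adjusted p was 1.46e-11 (adjusted p = 0.723 with an estimated correlation). ISG15, a ubiquitin-like modifier, stood at 18.1 and 21.9 FPKM in the controls and 91.8 in siE2F1, the helicase sensors DDX58 and IFIH1 had log2 fold changes of 0.88 and 0.63, and the signal transducers STAT2 and IRF9 of 0.59 and 1.23. MX1 (1.11, 1.04 and 0.968 FPKM) and USP18 (13.3, 13.3 and 11.3 FPKM) were the 2 below both controls. MX1, USP18, DDX58, IFIH1, STAT2 and IRF9 are named here after their values were seen.

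Androgen-related and lineage genes did not pass as groups. The list of androgen-response genes had 17 of 27 members above both controls and 8 below (median 0.14, camera adjusted p = 0.0977), with 8 higher and 2 lower adjusted over the list alone. ACPP, prostatic acid phosphatase, was at 62.6 and 65.2 FPKM in the controls and 146.1 in siE2F1 (log2 fold change 1.18, adjusted p = 0.103), and C1orf116 had a log2 fold change of 0.68. KLK3, which encodes PSA, was at 0.152, 0.0531 and 0.156 FPKM and is named here after its values were seen. Androgen-repressed genes, 6 measured, had a median of 0.34 (adjusted p = 0.169), with CCNG2 at 0.71 and OPRK1 at -0.48. With no filter on mean FPKM, which adds members of low level, that median was smaller. Luminal and prostate lineage genes had a median of 0.26 (adjusted p = 0.151), with the cell adhesion gene CDH1 at 0.60 and the transcription factor GATA2 at -0.56.

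Cell cycle regulators outside the called lists and stress genes gave smaller shifts. CDK inhibitors and G1 cyclins had a median of -0.12 (adjusted p = 0.151), with 5 of 12 lower adjusted over the list alone, led by CDKN2D, an INK4 inhibitor (-1.34), and CKS1B (-0.63). Among genes of at least 5 FPKM the median of this list was lower and the list passed (camera adjusted p = 0.0474). Of 37 listed histone genes 27 were measured. HIST1H4C, named here after its values were seen, was too low to test (1.09, 0.808 and 0.755 FPKM in control 0, control 1 and siE2F1). The measured histone genes split, 7 higher and 9 lower of 27 adjusted over the list alone, which does not describe histone expression as a whole. Their median was 0.10, their mean -0.04 and the test pointed up (adjusted p = 0.937), with HIST1H2BK at -1.23 and HIST1H2BM at -1.03; near-identical histone genes share reads, so single members are uncertain. Polycomb and chromatin regulators had a median of -0.03 (-0.10 and -0.06 against control 0 and control 1, adjusted p = 0.169), with HELLS at -0.86 and CBX2 at -0.62. The median was -0.07 for p53 targets (-0.05 and -0.11 against control 0 and control 1, adjusted p = 0.307), while SESN1, a sestrin induced by p53, was at 71.4 and 75.3 FPKM in the controls and 146.5 in siE2F1 (adjusted p = 0.111), and PLK3 stood at -0.53. Apoptosis genes had a median of -0.03 (adjusted p = 0.718; 0.02 against control 0 alone), with PMAIP1 at -0.81 and BCL2L11 at -0.65, 2 BH3-only genes. The unfolded protein and ATF4 list had a median of -0.14 (adjusted p = 0.169), with EDEM1, of endoplasmic reticulum-associated degradation, at -1.23 and CHAC1 at -0.69.

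Metabolic, structural and marker lists did not pass either. The median was 0.13 for cholesterol synthesis (adjusted p = 0.152; HMGCS1 0.37, MSMO1 -0.36) and 0.13 for the 5 measured inflammatory genes (0.05 against control 0 alone and 0.17 against control 1 alone, adjusted p = 0.822; NFKB1 0.38, SOD2 -0.23). Fatty acid synthesis had a median of 0.005, while the controls differed by -0.18 (-0.05 and 0.10 against control 0 and control 1, adjusted p = 0.937; ACACA 0.54, ACSL1 0.42). Hypoxia and glycolysis genes had a median of -0.23 with the controls 0.17 apart (-0.10 against control 0 alone and -0.29 against control 1 alone, adjusted p = 0.151; SLC2A1, a glucose transporter, -0.90, LDHA -0.63). Mesenchymal markers, 5 measured, had a median of -0.23 with the controls -0.22 apart (-0.34 and -0.12 against control 0 and control 1, adjusted p = 0.357; FN1 -0.86, TAGLN 0.84). Housekeeping genes had a median of -0.05 (adjusted p = 0.307), with GAPDH at -0.55 and B2M, the light chain of class I antigen presentation, at 0.55. Cytosolic ribosomal proteins (median 0.06, 0.08 and 0.02 against control 0 and control 1, adjusted p = 0.169; RPS15 -0.38, RPS27 0.32) and oxidative phosphorylation (median -0.05, -0.008 and -0.08 against control 0 and control 1, adjusted p = 0.288; CYC1 -0.38, SDHC -0.37) stayed near 0; many ribosomal protein genes and GAPDH have processed pseudogenes that share reads. Neuroendocrine (3 measured, ENO2 -0.51, DDC 0.31), basal (2 measured, ITGB4 0.20, ITGA6 -0.06) and leukocyte markers (3 measured, CD8A 0.31, LYZ 0.08) had too few members for the list test. With an estimated correlation the adjusted p of the 22 tested lists was 0.723 or more. Among 10000 random lists matched on expression, some medians of lists that did not pass were still extreme, at percentile 99.88 for luminal, 99.66 for androgen-repressed and 98.74 for androgen-response genes, 0.88 for the unfolded protein and ATF4 list and 0.36 for hypoxia and glycolysis. For hypoxia and glycolysis the median difference between the controls was itself at percentile 100.

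**Figure D2:**
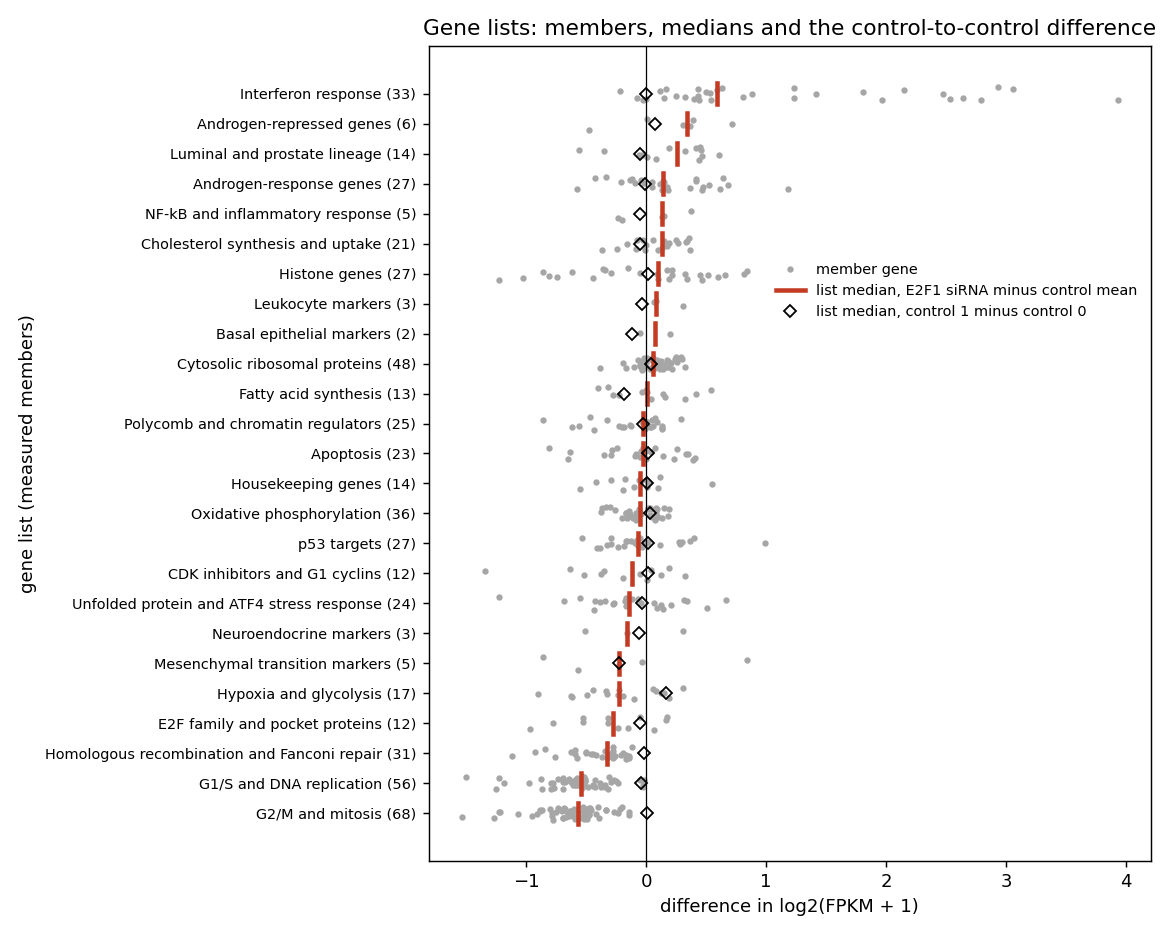
Difference in log2(FPKM + 1) between siE2F1 and the control mean for each measured gene of the 25 lists (grey points), with the list median (red line) and the median difference between control 1 and control 0 (open diamond). The G2/M median lies at -0.57 and the interferon median at 0.59, with their control differences at 0.004 and 0.001.

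By size alone, 227 genes lay at least 2-fold beyond both controls, 107 above and 120 below. With control 0 or control 1 in the place of siE2F1 the same rule gave 134 and 109 genes. Without small RNA genes siE2F1 had 117 such genes, 41 above and 76 below, against 17 and 22 for the controls.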

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

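Leaving out small RNA genes was chosen after seeing the data; the other settings were planned. E2F1 was lower in siE2F1 under each setting (log2 fold change -2.59 to -2.11), but its call was lost with a pseudocount of 0.1 (-2.59, adjusted p = 0.0601) and with no filter on mean FPKM (-2.12, adjusted p = 0.159). A pseudocount of 0.1 left 18 genes called, 7 of them higher, and gave 369 genes at least 2-fold beyond both controls, 220 of them below. With no filter limma called 0 genes, 0 higher and 0 lower, of 21691, with 4862 at an unadjusted p under 0.05. A minimum of 5 FPKM gave 26 genes called higher and 71 at least 2-fold above both controls. Without small RNA genes 1467 genes were called, 581 higher and 886 lower, and 117 lay at least 2-fold beyond both controls, 41 above and 76 below. Leaving out a control makes the size rule easier to meet, since 1 library fewer must be passed: 393 to 421 genes in all, 191 to 193 above and 202 to 228 below; with no residual degree of freedom these are values with no test. The number of gene lists called was 5 under each setting that tested lists with the preset correlation, although at 5 FPKM the CDK inhibitor list took the place of the E2F family list. It was 0 with an estimated inter-gene correlation, where all 5 lost their call. That setting has 1 degree of freedom and could hardly call any list, so it tests little. Common-median scaling shifted no library and so tests nothing. Quantile normalization tests little, since the sorted values were already near identical. No result changed sign while called. Over the tested settings, 440 values of named genes kept direction and side of the threshold, 54 gained a call and 14 lost it. Of the 440, common-median scaling gave 75 and quantile normalization 75, and 50 of the 54 gains came from leaving out small RNA genes. Of list values tested with the preset correlation 151 kept direction and side, 1 gained and 1 lost a call. A further 2 lists tested only with no filter moved, of which the basal markers changed sign. With a control left out, which gives no test, 149 of 150 named gene values and 48 of 50 list medians kept their sign, the exceptions being ITGA6, apoptosis and fatty acid synthesis. Apart from fewer genes tested or fewer controls to pass, the cause was not tested. No paired analysis was possible with 1 siE2F1 library, which also shares no number with the controls in its label. Depth is unknown, so its effect cannot be given.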

Other observations

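The gene lists in the first paragraph, the leukocyte test, the test of rearranged sequences and every count without small RNA genes were chosen after results had been seen; the other tests were set before. Genes for chromosome architecture, a list added after HMGB2 had been seen among the lower genes, lay below both controls in all 18 measured members (median log2 fold change -0.44, camera adjusted p = 8.91e-08; adjusted p = 0.277 with an estimated correlation). HMGB2, a chromatin-bound HMG-box protein, was at 113.4 and 115.3 FPKM in the controls and 46.7 in siE2F1, HMGB3 at 18.5, 19.0 and 9.51 FPKM, and STMN1, a regulator of microtubules, at 77.3, 78.7 and 47.3 FPKM. Adjusted over the list alone 12 of the 18 fell and 0 over all genes tested. Spliceosomal Sm and snRNP proteins (median -0.16, 13 of 17 below both controls) and nucleotide synthesis enzymes (median -0.13, 14 of 19; -0.21 against control 0 alone and -0.06 against control 1 alone) were called lower too (adjusted p = 0.0036 for each; adjusted p = 0.277 with an estimated correlation). Adjusted over the list alone, 1 member fell in each. The lowest were SNRPB, at 148.0, 147.8 and 55.3 FPKM, and IMPDH1, of guanine nucleotide synthesis, at 30.7, 29.5 and 10.6 FPKM, the genes that prompted these lists, so the calls partly restate them; without SNRPB, IMPDH1 and HMGB2 the adjusted p was 0.0125, 0.012 and 4.61e-07 (adjusted p = 0.292 for each with an estimated correlation). Of 16 listed antigen presentation genes, 6 were present in the data and 5 were measured, so most of that list was untested. The 5 measured genes did not pass (median -0.07, camera adjusted p = 0.592, and adjusted p = 0.754 with an estimated correlation). Their median was -0.043 against control 0 alone and -0.051 against control 1 alone.

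The lower level of the 3 cell cycle lists was weighed against a trend with transcript length, GC content or expression. Removing that trend left the median of the 154 members with a value at -0.529 (-0.528 before), with a median absolute deviation of 0.206, which argues against the trend as the cause. Direct matches in 3′ UTRs to the sequences described further down are argued against as well. The 123 members with neither sequence had a median of -0.523, and the 31 with either, CDCA8 and CDC25A among them, -0.546. The siRNA sequences are not given, so this split cannot exclude other seeds or an indirect effect of seed matches in other genes. Another difference of the single siE2F1 culture, such as its density at harvest, cannot be told apart from the loss of E2F1, because the number of siE2F1 libraries is 1. Lower E2F1 activity itself, which the design names, stays open as a hypothesis.

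The higher level of the interferon list kept its median after the same trend was removed (0.606, against 0.592 before), with a bootstrap 95% interval of 0.421 to 1.25 over members whose median absolute deviation was 0.794; the trend explained 1.95% of the variance over genes. RNA from leukocytes in the siE2F1 library was tested with the 5 leukocyte markers found in the files, whose median rise over the higher control was 0.186 FPKM. The highest was CD8A (0.702 FPKM), CD68 and LYZ lay 0.203 and 0.186 FPKM above, and CD4 and PTPRC lay below (-0.0221 and -0.726 FPKM), against a median rise of 4.25 FPKM over the 33 interferon genes, which argues against leukocyte RNA as the cause. A response of the cells to the siRNA pool rather than to loss of E2F1 cannot be told apart from an effect of E2F1, since the number of siRNA pools against E2F1 is 1; transfected RNA may induce these genes. Nor can another difference of the single siE2F1 culture be told apart from these. An effect of lower E2F1 on interferon genes stays open as a hypothesis. More siE2F1 cultures, with another siRNA against E2F1 or a rescue, would be needed to test it.

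Many genes outside the cell cycle lists were lower in siE2F1, and shared short sequences in 3′ UTRs may account for part of them. Over 10323 genes outside the cell cycle and E2F lists, GAAACTG had a z of -11.34 and CCCTGTT of -10.34, against -5.28 to 5.21 over 200 permutations; between the controls z ran from -6.41 to 6.83 over all sequences, a wider background, with -1.39 and -3.97 for these. GAAACTG occurs in the E2F1 transcript, as do 13.4% of the sequences, and so does AACAGGG, the reverse complement of CCCTGTT, as seeds of the guide and passenger strands of siRNAs against E2F1 would need. The 13.4% leaves out reverse complements, and the share with a match in either orientation was not computed. The siRNA sequences are not given in the sources used here. The median log2 fold change was -0.05 in genes with either sequence and 0.02 in genes with neither. Either was in 25.3% of the genes searched, in 42.6% of the 652 lower and in 18.0% of the 384 higher calls without small RNA genes. Of the 12 named lower genes searched outside the lists, 9 held either, among them ARL6IP1, TSPAN7, NRAS and ADAM10. These shares are no separate test, since the sequences were picked on these genes and long 3′ UTRs hold them more often. The values argue against length or base composition of the 3′ UTR as the cause: with no regression on them, GAAACTG and CCCTGTT had a z of -10.51 and -10.43, and the lowest of 540 other arrangements of the same bases was -3.59, within the permutations (-5.04 to 5.06).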
